A study of Homo sapiens with 4 samples.

How the data were processed

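The series holds RNA-seq of GES-1 cells in 4 libraries: 2 from cells given N-methyl-N'-nitro-N-nitrosoguanidine (MNNG) and 2 from cells given phosphate-buffered saline (PBS). GES-1 is described as an immortalised line of human gastric epithelial cells, an identity that was not tested here. MNNG is an alkylating agent that methylates DNA bases. Per the labels' protocols, MNNG was used at 200 µmol/L for 48 h, and both treatments were made up in 0.3% DMSO. The labels give no time for the PBS cells, and they call the treated libraries PLGC cells without spelling the term out. They give WT as the genotype of the PBS samples only. They do not say how long the treated cells were grown after the exposure.

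The authors deposited a single table of 20284 genes, identified by Ensembl gene IDs and symbols. Per the file headers it holds a read count per gene and library, FPKM per library and as group means, a log2 fold change, a p-value and a false discovery rate for MNNG against PBS, and KEGG, GO and transcription factor family annotation. The count columns held whole numbers that the authors had not normalized, and the tests below start from them. The deposited mean FPKM, log2 fold change, p-value and false discovery rate are the authors' own, and the test behind them is not given in the sources used here. Genes without counts in a group carry small values above 0 in the deposited mean FPKM, of at most 0.0095 in the PBS mean for genes without PBS counts, so the authors' deposited fold changes of such genes rest on that replacement. Another 4 columns of FPKM per library were not used. The genome build was GRCh38 per the submitters' processing notes. The aligner, the counting tool, the annotation and the strand setting are not given in the sources used here.

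The MNNG count columns carry the replicate numbers 1 and 2 of the sample titles. The PBS columns are numbered differently from the PBS titles, so they were assigned to the group only and are called PBS A and PBS B. Total counts were 16682087 in PBS A, 15660027 in PBS B, 17779727 in MNNG 1 and 16829485 in MNNG 2. A count of 3 then stands for 0.169 to 0.192 CPM (counts scaled to the library total) before scaling. For genes with no counts in a group, the fold was computed against 3 counts summed over that group, and ratios with few counts carry an exact 95% binomial interval. Such bounds and intervals cover counting error only. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Pairs of libraries were compared by a chi-square statistic over genes with at least 10 counts in the pair.

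Genes were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr with the group, TMM scaling, trended dispersions, and the quasi-likelihood F test (glmQLFit and glmQLFTest) over the 4 libraries with no covariate. P-values were adjusted with the Benjamini-Hochberg method, and a gene was called changed at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were back-calculated from the F test, as the absolute log2 fold change over the square root of F. Without a stated strand setting, reads of overlapping and antisense genes may have been shared between genes. Of the genes deposited, 953 share a symbol with another gene and 112 have none, and 4008 had no count in any library. Coordinates, transcript lengths and GC content came from GENCODE release 29 (GRCh38), in which 20090 of the 20284 IDs were found, 19712 of them as protein-coding genes.

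The gene lists, the tests, the alternatives and the rule for naming genes were set before the data were examined. The 42 lists cover the genes of the series title, intestinal, gastric and stem cell markers, signalling targets, DNA repair, cell cycle, stress, metabolism and markers of other cell types. The 37 lists with at least 5 tested members were tested on log2 CPM (prior count 2) with camera from limma 3.58.1 at a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Beside it stand camera with an estimated correlation and fry, which asks whether a list moves one way on balance without comparing it with other genes. None of the 37 lists passed camera with an estimated correlation. Over-representation of the deposited KEGG and GO process terms with 10 to 500 members was tested with a one-sided Fisher's exact test against the annotated tested genes, separately for higher and lower genes.

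Genes were named by 3 rules: the 4 genes of the series title; the 8 largest increases and 8 largest decreases among called genes with a mean log2 CPM of at least 3, a symbol and no overlap between the groups' libraries, leaving out pseudogenes and sex-linked marker genes; and up to 4 called members of each list with the largest changes. A list with fewer than 2 called members could give its member with the smallest adjusted p. Genes named outside these rules are marked as chosen after their values were seen. One list member that these rules would name is not reported here.

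Alternatives were RLE factors, upper-quartile scaling and library size alone in place of TMM; no filter or a CPM of at least 1 in all libraries; DESeq2 1.42.0, limma-voom, the robust and the legacy quasi-likelihood fits and glmTreat at 1.5-fold; a prior count of 0.5 for the lists; terms of 5 to 300 members and calls of at least 2-fold for the terms; and leaving out each library in turn. The steps were tested on 5 simulated data sets with 200 changed genes drawn from the means and depths of these libraries (12732 genes tested). The test recovered 44.4% of genes changed 1.5-fold, 85.8% of those changed 2-fold and 98.0% of those changed 4-fold, and 6.82% of its calls were false. Both groups were simulated with the same dispersion trend and no spread particular to single genes. The library pairs of this series differed in spread and more genes were called, so these rates may not hold for them. The 2-against-2 design compares groups too small for counting other splits of the samples.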

Results

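RNA-seq profiles were collected from GES-1 cells, described as an immortalised human gastric epithelial line, after MNNG, a DNA-methylating carcinogen (2 libraries), or PBS (2 libraries). Total counts ranged from 15660027 to 17779727 per library, and 14586 to 14921 genes had at least 1 count. Mitochondrially encoded genes took 3.93% to 4.80% of the counts, and the 10 most abundant genes took 5.08% to 5.74%. Log2 CPM correlated across genes at 0.983 between PBS A and PBS B and at 0.990 between MNNG 1 and MNNG 2, against 0.950 to 0.954 between libraries of different groups; genes are not independent replicates. Counts of the PBS pair differed more than those of the MNNG pair, with a chi-square per degree of freedom of 23.1 against 3.72. Both pairs differed by more than sampling noise, and all 4 libraries were kept as separate replicates.

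The comparison of MNNG with PBS asks which genes differ between carcinogen-treated and control GES-1 cells. Among 12791 tested genes, 4828 were called changed by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 2459 higher and 2369 lower in MNNG cells. At least 2-fold changes were called for 1168 genes, 419 higher and 749 lower. With library size alone in place of TMM scaling, the median log2 fold change of all genes moved from -0.01 to -0.18. The split of all calls was then 1454 higher (28.8%) and 3590 lower, against 50.9% higher with TMM. The split of 2-fold calls was 272 higher and 1107 lower. The number of calls rested on the MNNG libraries: it was 1424 without MNNG 1 and 971 without MNNG 2, where the spread came from the PBS pair alone, and 6845 without PBS A and 6747 without PBS B.

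**Figure D1:**
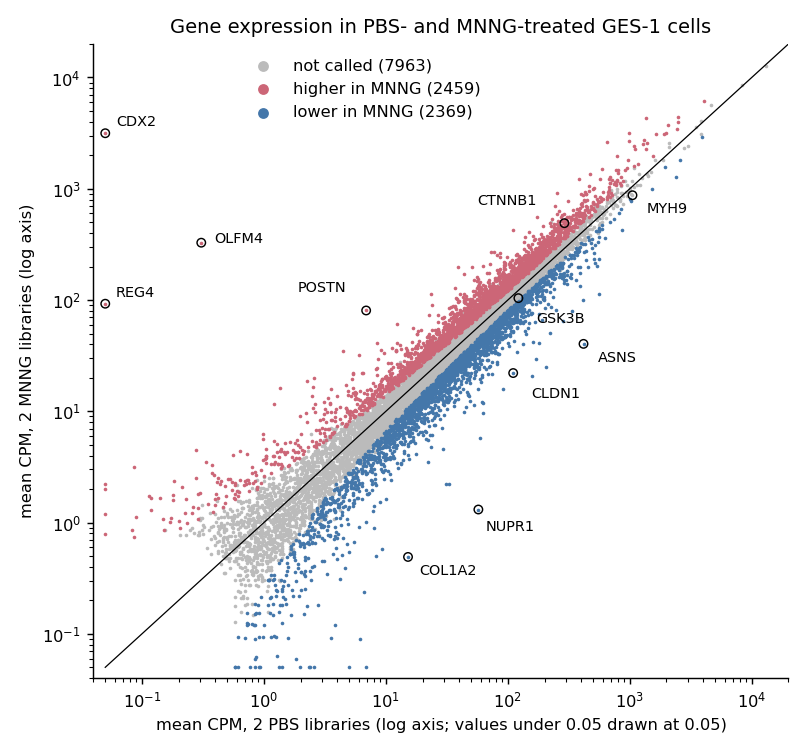
Mean CPM of each tested gene in the PBS libraries (x axis) and the MNNG libraries (y axis), both on log axes, with 1 point per gene coloured by its call and the diagonal marking equal levels. CDX2, REG4 and OLFM4 lie far above the diagonal, with 0, 0 and 10 counts in the PBS libraries, and NUPR1 and COL1A2 lie far below it.

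Of the 4 genes in the series title, OLFM4 and CTNNB1 were higher in MNNG cells, and MYH9 and GSK3B did not pass the test. OLFM4, a secreted glycoprotein of intestinal stem cells (ENSG00000102837, chromosome 13, 53028759 to 53052057, GRCh38, protein-coding), had 0 and 10 counts in the PBS libraries and 5305 and 5366 in the MNNG libraries. Its summed counts gave a ratio of 1123 after scaling (95% interval 610 to 2342), and its level in MNNG cells was 327 ± 18.3 CPM (SD, n = 2). The size of that ratio rests on the 10 counts of PBS B: the log2 fold change was 9.04 without PBS A, and without PBS B no PBS count was left. CTNNB1, which encodes β-catenin (ENSG00000168036, chromosome 3, 41194741 to 41260096), rose from 291 ± 8.38 to 490 ± 2.81 CPM (SD, n = 2 per group), a 1.69-fold change. The adjusted p of edgeR's quasi-likelihood test was 1.25e-05 for OLFM4 and 0.00109 for CTNNB1. MYH9, the heavy chain of non-muscle myosin IIA (ENSG00000100345, chromosome 22, 36281277 to 36388067), was at 874 ± 7.09 CPM in MNNG and 1052 ± 194 CPM in PBS cells (SD, n = 2 per group). Its log2 fold change was -0.27 (SE 0.13, adjusted p = 0.139, edgeR). GSK3B, a kinase that marks β-catenin for degradation (ENSG00000082701, chromosome 3, 119821323 to 120094417), was at 104 ± 2.41 CPM in MNNG and 122 ± 10.6 CPM in PBS cells (SD, n = 2 per group). Its log2 fold change was -0.23 (SE 0.10, adjusted p = 0.117, edgeR). Without PBS A the log2 fold change was -0.45 for MYH9 and -0.32 for GSK3B, and without PBS B it was -0.08 and -0.16. Such fits hold a single PBS library and take their spread from the MNNG pair, so they do not measure the PBS spread. MYH9 was at 915 CPM in PBS A and 1189 CPM in PBS B. With library size alone and all libraries, both genes passed edgeR's test, at -0.43 and -0.40.

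**Figure D2:**
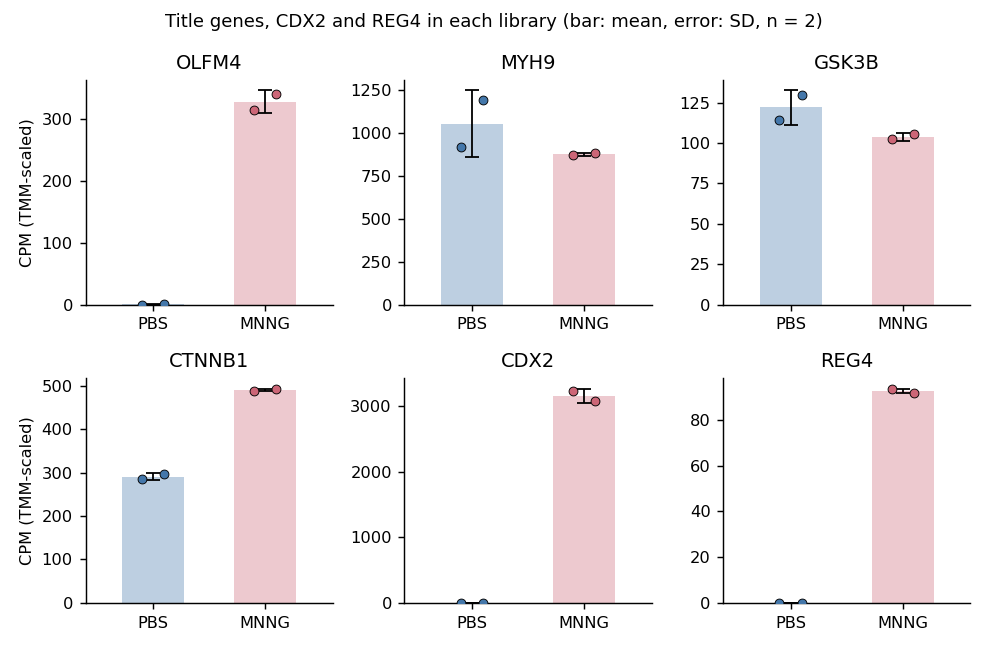
CPM after TMM scaling of the title genes, CDX2 and REG4 in each library (points), with the group mean as a bar and the SD as an error bar (n = 2). OLFM4, CDX2 and REG4 were near 0 in both PBS libraries, CTNNB1 was higher in both MNNG libraries, and the PBS libraries of MYH9 spread by 194 CPM (SD).

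CDX2 and REG4 were the only members of the intestinal marker list called changed. CDX2, a homeobox transcription factor that specifies intestinal epithelium (ENSG00000165556, chromosome 13, 27962137 to 27971139), had no counts in either PBS library and 54475 and 48545 counts in the MNNG libraries. At 3155 ± 106 CPM (SD, n = 2) it ranked 14 among all genes of the table, and it was at least 36136-fold higher than in PBS cells, against a floor of 3 counts over the PBS group. REG4, a secreted lectin of enteroendocrine and goblet cells (ENSG00000134193, chromosome 1, 119794018 to 119811660), had no counts in PBS cells and 92.6 ± 0.998 CPM in MNNG cells (SD, n = 2), at least 1060-fold higher. The adjusted p of edgeR's test was 5.90e-07 for CDX2 and 1.25e-05 for REG4. Of the 21 intestinal markers listed, 12 had no counts in any library, among them CDX1, TFF3, KRT20 and FABP1. MUC2, the goblet cell mucin, had 3 counts in each MNNG library and none in PBS. The remaining tested member, the peptidase ANPEP, had a log2 fold change of -0.30 (adjusted p = 0.298, edgeR). Of 19 gastric markers, 10 had no counts and 4 were tested. None was called changed, and the smallest adjusted p in edgeR's test was that of the mucin MUC1 (0.284, log2 fold change -0.26). All gastric markers together summed to 15.8 CPM in PBS and 14.9 CPM in MNNG cells, so a fall could hardly be seen. CDX1, TFF3, KRT20, FABP1 and MUC2 were named after their values were seen.

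Stem cell markers and Wnt target genes were higher in MNNG cells. Of 10 tested gastrointestinal stem cell markers, 8 rose and none fell (8 adjusted over the list alone). Besides OLFM4 they included LGR5, a receptor for R-spondins, at a log2 fold change of 2.70 (SE 0.42), and EPHB3, an ephrin receptor of the crypt base, at 1.86 (SE 0.33). Of 16 tested Wnt/β-catenin targets, 10 rose and none fell (10 rose and 1 fell adjusted over the list alone). Among them were AXIN2, a feedback inhibitor of the pathway, at 1.70 (SE 0.31), and DKK1, a secreted Wnt antagonist, at 1.52 (SE 0.28). The sizes of several of these changes depended on the PBS library used. LGR5, with 9 and 24 counts in the PBS libraries, was at 2.08 without PBS A and 3.62 without PBS B. EPHB3 was at 1.36 and 2.52, DKK1 at 1.09 and 2.10, and AXIN2 at 1.63 and 1.76. The tested genes LGR5, TNFRSF19 and CD44 belong to both lists; CD44 was chosen after its value was seen. TNFRSF19 lost its call whichever library was left out (adjusted p of 0.0671 to 0.149, edgeR), and CD44 was not called without MNNG 1 (0.163) or without MNNG 2 (0.276). The median log2 fold change was 0.99 for the stem cell list (camera with Benjamini-Hochberg, adjusted p = 0.000972) and 0.46 for the Wnt list (0.00518). The stem cell median was 0.43 with no filter (adjusted p = 0.0191) and 0.43 with a CPM of at least 1 in all libraries (0.0201), which change the members tested. Neither list was called by the other form of camera: adjusted p = 0.737 with an estimated correlation for the stem cell list and adjusted p = 0.470 with an estimated correlation for the Wnt list. Without MNNG 1, and likewise without MNNG 2, 4 members of each list rose.

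The ATF4 and integrated stress response list, which holds amino acid synthesis and transport genes and the ATF4 and CHOP factors, fell most of the 42 lists by its median. Of 28 tested members, 24 fell and 1 rose (25 and 1 adjusted over the list alone), with a median log2 fold change of -1.43. NUPR1, a stress-induced transcription cofactor, went from 57.3 ± 5.26 to 1.31 ± 0.328 CPM (SD, n = 2 per group), a log2 fold change of -5.44 (SE 0.21). SLC6A9, a glycine transporter, fell by 3.82 (SE 0.22), and ASNS, asparagine synthetase, fell by 3.37 (SE 0.22) on the log2 scale. The mitochondrial folate enzyme ALDH1L2 fell by 3.06 (SE 0.11), and PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, fell by 2.94 (SE 0.13). ATF4 itself, named after its value was seen, was at -0.41 (SE 0.10, adjusted p = 0.0150, edgeR), and that call was lost without MNNG 1 (adjusted p = 0.158) and without MNNG 2 (0.234). The member that rose was ATF5, at 0.68 (SE 0.14), also named after its value was seen; its call was lost without MNNG 1 (0.0818) and without MNNG 2 (0.0937). The list passed camera (adjusted p = 4.00e-13 with Benjamini-Hochberg; adjusted p = 0.665 with an estimated correlation). It lay 0.40 higher in PBS A than in PBS B by its median, and 20 members fell without MNNG 1 and 19 without MNNG 2.

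**Figure D3:**
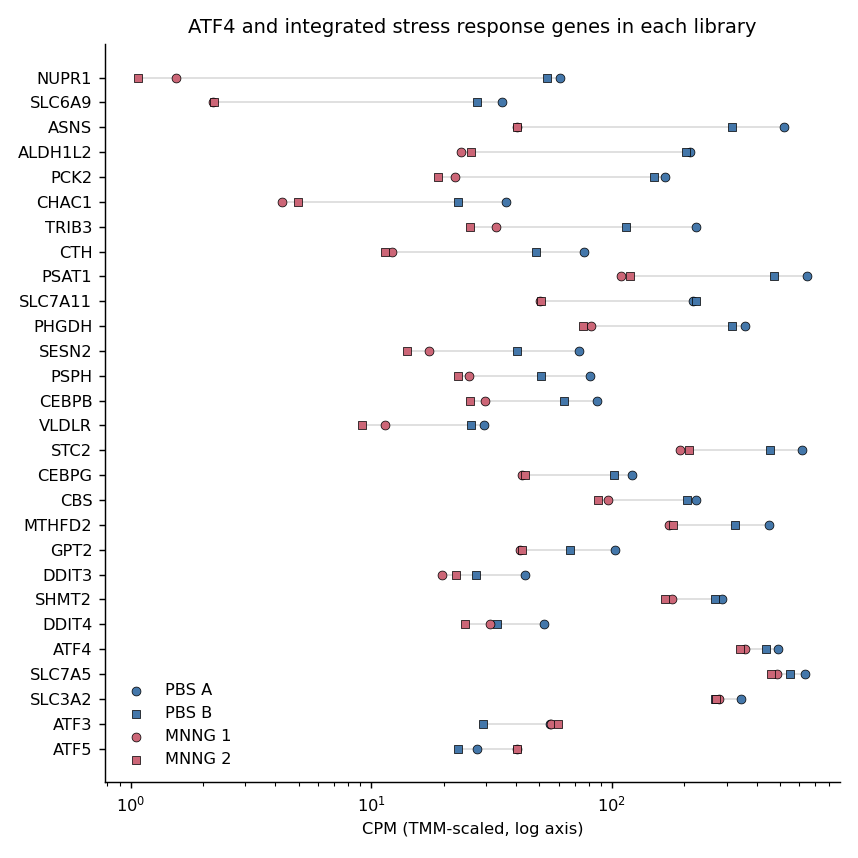
CPM after TMM scaling, on a log axis, of the 28 tested ATF4 and integrated stress response genes in each library, ordered by fold change with the largest decrease at the top. For 25 of the 28 genes both MNNG libraries lie below both PBS libraries.

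Outside that list, the largest decreases included ADM2, a calcitonin-family peptide hormone, at a log2 fold change of -3.87 (SE 0.33), and LAMP3, a lysosomal membrane protein, at -3.36 (SE 0.20). COL1A2, a chain of type I collagen, was at -4.95 (SE 1.26, adjusted p = 0.0186, edgeR), with 501 and 42 counts in the PBS libraries and 8 in each MNNG library. Its call was lost without MNNG 1 (adjusted p = 0.0751) and without MNNG 2 (0.0821), and its log2 fold change was -2.38 without PBS A. Increases after CDX2, REG4 and OLFM4 were led by SHISA3, of a family that retains Wnt and FGF receptors in the cell, at 3.60 (SE 0.29), and POSTN, the matrix protein periostin, at 3.54 (SE 0.15). The membrane proteolipid MALL followed at 2.98 (SE 0.28) and the transcription factor FOS at 2.93 (SE 0.23). A gene with the symbol KLC1 (ENSG00000256500), at 3.09 (SE 0.39), overlaps another gene with that symbol (ENSG00000126214, log2 fold change -0.01), so its reads are uncertain. The other largest changes named here kept their call without any one library.

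More p53 targets fell than rose in MNNG cells. Of 31 tested p53 targets, 17 fell and 4 rose (20 and 4 adjusted over the list alone), with a median log2 fold change of -0.62. GDF15, a stress cytokine, fell by 2.01 (SE 0.34) and BBC3, a BH3-only death gene, fell by 1.96 (SE 0.32). CDKN1A, the CDK inhibitor p21, named after its value was seen, fell by 1.40 (SE 0.26); its call was lost without MNNG 2 (adjusted p = 0.0564, edgeR) and its log2 fold change was -0.86 without PBS A. The members that rose were SERTAD1 (1.65), PLK2 (1.54), TIGAR (0.80) and PPM1D (0.58), the last 3 named after their values were seen; TIGAR was not called without MNNG 2 (adjusted p = 0.0983, edgeR), nor PPM1D without MNNG 1 (0.0887) or without MNNG 2 (0.139). The list passed camera (adjusted p = 0.00113 with Benjamini-Hochberg; adjusted p = 0.739 with an estimated correlation) but not fry (adjusted p = 0.171). Its median lay 0.40 higher in PBS A than in PBS B; it was -0.31 without PBS A (camera, adjusted p = 0.0440) and -0.87 without PBS B. Without PBS A 16 members fell and 7 rose, without PBS B 26 fell, without MNNG 1 9 fell and 3 rose, and without MNNG 2 5 fell and 2 rose.

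DNA repair lists did not pass with all 4 libraries. Of 22 direct reversal and base excision repair genes, 6 fell and 2 rose (6 and 2 adjusted over the list alone; camera, adjusted p = 0.236). ALKBH2, which reverses methylated bases, was at -1.12 (SE 0.23), a call lost without MNNG 2 (adjusted p = 0.0950, edgeR). MGMT, which removes methyl groups from guanine, was at -0.16 (SE 0.25, adjusted p = 0.645) and was chosen after its value was seen; it ranged from -0.37 without MNNG 1 to 0.02 without MNNG 2. Of 19 mismatch repair genes 4 fell and 3 rose (4 and 4 adjusted over the list alone; camera, adjusted p = 0.853, where the median of 0.05 and the mean of -0.01 differ in sign). Of 28 recombination, Fanconi and checkpoint kinase genes 7 fell and 3 rose (7 and 3 adjusted over the list alone; camera, adjusted p = 0.0886), and this list passed without PBS A (median -0.22, adjusted p = 0.0106). At most 1 member of any of these 3 lists fell, and at most 1 rose, without MNNG 1 or without MNNG 2. Recombination and Fanconi genes that fell numbered 14 without PBS A and 15 without PBS B (where 7 rose), mismatch repair genes that rose numbered 8 without PBS A and those that fell 7 without PBS B, and 4 base excision genes rose without PBS A.

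More G2/M genes rose than fell, and most were not called. Of 30 G2/M genes 8 rose and 1 fell (8 and 1 adjusted over the list alone), among them CDC20, an activator of the anaphase-promoting complex, at 0.86 (SE 0.10), and CCNB1, cyclin B1, at 0.71 (SE 0.09). CDK1, the kinase partner of cyclin B, was the member that fell, at -0.39 (SE 0.09, chosen after its value was seen); it was not called without MNNG 1 (adjusted p = 0.197, edgeR) or without MNNG 2 (0.191). The list median was 0.25 (camera, adjusted p = 0.00807; adjusted p = 0.739 with an estimated correlation), and camera's call was lost without PBS A (median 0.14, adjusted p = 0.193). Fry did not call it (adjusted p = 0.171). With library size alone its median was 0.07. Members that rose numbered 15 without PBS A, 19 without PBS B, 3 without MNNG 1 and 2 without MNNG 2. Replication and G1/S genes had a median log2 fold change of 0.22, against 0.07 without PBS B and 0.04 with library size alone. Of 30 such genes 12 rose and 6 fell (13 and 6 adjusted over the list alone, camera adjusted p = 0.109), led by CCNE1, cyclin E1, at 1.87 (SE 0.18). Without PBS A 18 of these rose and the list passed camera (median 0.34, adjusted p = 0.0117), and 4 rose without MNNG 1 and 3 without MNNG 2, with none falling.

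More mesenchymal genes rose than fell, and the epithelial list did not pass the test. Of 20 mesenchymal transition genes 9 rose and 2 fell (11 and 3 adjusted over the list alone), with a median log2 fold change of 0.49. SPARC, a matrix glycoprotein, was at 1.68 (SE 0.15), SNAI1, a repressor of epithelial genes, at 1.48 (SE 0.22), and TGFBI, a matrix adaptor protein, at 1.41 (SE 0.20). The members that fell were FN1, fibronectin, at -0.92 (SE 0.19) and the gelatinase MMP2 at -0.86 (SE 0.26), both chosen after their values were seen and neither called without MNNG 1 or without MNNG 2 (adjusted p of 0.0805 to 0.180, edgeR), nor MMP2 without PBS A (0.120); FN1 was at -0.58 without PBS B. Camera gave an adjusted p of 0.0149 (adjusted p = 0.739 with an estimated correlation), lost without PBS A (median 0.23, adjusted p = 0.206), and fry did not call the list (adjusted p = 0.179); the list median lay 0.43 lower in PBS A than in PBS B. Without PBS A 5 members fell, without PBS B 15 rose, and without MNNG 1 and MNNG 2 5 and 4 rose. Of 17 epithelial genes 6 fell and 3 rose (6 and 3 adjusted over the list alone; camera, adjusted p = 0.141). CLDN1, a tight junction claudin, fell by 2.33 (SE 0.21), and KRT8, a simple epithelial keratin, rose by 1.30 (SE 0.15). Without PBS A 10 epithelial genes fell; 4 fell and 1 rose without MNNG 1, and 1 fell and 1 rose without MNNG 2. E-cadherin (CDH1), chosen after its value was seen, had a log2 fold change of -1.33 (SE 0.52, adjusted p = 0.0795, edgeR), at 0.692 ± 0.530 CPM in MNNG and 1.78 ± 0.166 CPM in PBS cells (SD, n = 2 per group). It was at -2.46 without MNNG 1 and at -0.73 without MNNG 2, and was called in neither.

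Protein folding genes of the endoplasmic reticulum and the cytosol rose, while the ATF4 list fell. Of 22 ER chaperone and unfolded protein response genes, 13 rose and 2 fell (13 and 4 adjusted over the list alone), with a median of 0.92. CRELD2, an ER stress protein, was at 1.95 (SE 0.15), the disulfide isomerase PDIA4 at 1.86 (SE 0.09) and HSPA5, the chaperone BiP, at 1.44 (SE 0.10). XBP1, the transcription factor of this response, at -0.59 (SE 0.16), and the ubiquitin ligase SYVN1, at -0.42 (SE 0.12), fell; both were chosen after their values were seen, and neither was called without MNNG 1 or without MNNG 2 (adjusted p of 0.107 to 0.256, edgeR). XBP1 was at -0.31 without PBS A and at -0.84 without PBS B. Of 20 heat shock genes, 17 rose and none fell (17 adjusted over the list alone), with a median of 0.69. HSPB1, a small heat shock protein, was at 1.81 (SE 0.12) and HSP90AA1, the inducible cytosolic HSP90, at 1.68 (SE 0.11). Camera gave adjusted p = 0.000324 for the ER list (adjusted p = 0.599 with an estimated correlation) and 2.04e-07 for the heat shock list (adjusted p = 0.470 with an estimated correlation). Members of the ER list that fell numbered 5 without PBS A, 6 without PBS B and 0 without either MNNG library. Heat shock genes that rose numbered 9 without MNNG 1 and 5 without MNNG 2.

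Glycolysis, hypoxia, cholesterol and lipid genes also rose. All 18 glycolysis genes were tested, of which 15 rose and 1 fell (15 and 1 adjusted over the list alone; median 0.81), with LDHA, lactate dehydrogenase A, at 2.02 (SE 0.10) and the aldolase ALDOC at 1.79 (SE 0.17). ENO2, the neuronal enolase, fell by 0.52 (SE 0.13), a call lost without MNNG 1 (adjusted p = 0.0862, edgeR) and without MNNG 2 (0.216). Of 25 hypoxia response genes, 17 rose and 1 fell (19 and 1 adjusted over the list alone; median 0.73). STC1, a secreted hormone, was at 2.46 (SE 0.22), the mitophagy receptor BNIP3 at 1.97 (SE 0.11) and the collagen prolyl hydroxylase P4HA1 at 1.97 (SE 0.14). VEGFA, the angiogenic growth factor, fell by 0.95 (SE 0.14) and was chosen after its value was seen. Of 24 cholesterol synthesis genes, 21 rose and none fell (22 adjusted over the list alone; median 0.87), with HMGCS1, a synthase early in the pathway, at 1.65 (SE 0.10). Of 21 fatty acid and lipid genes, 12 rose and 2 fell (13 and 3 adjusted over the list alone; median 0.49), led by the desaturase SCD at 1.45 (SE 0.15). The camera adjusted p was 5.66e-07 for glycolysis (adjusted p = 0.470 with an estimated correlation) and 1.68e-06 for hypoxia (adjusted p = 0.470 with an estimated correlation). It was 3.02e-09 for cholesterol synthesis (adjusted p = 0.599 with an estimated correlation) and 0.00146 for lipids (adjusted p = 0.470 with an estimated correlation). Without MNNG 1, 9 glycolysis, 10 hypoxia, 12 cholesterol and 4 lipid genes rose; without MNNG 2 the numbers were 9, 11, 12 and 3.

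Camera also called the ribosome biogenesis, respiratory chain and chromatin lists, of which fry called the chromatin list alone. Of 26 ribosome biogenesis genes 11 rose and none fell (11 adjusted over the list alone; median 0.31), with the nucleolar proteins NOP56 at 0.95 (SE 0.12) and NPM1 at 0.89 (SE 0.10). Of 30 nuclear oxidative phosphorylation genes 13 rose and 1 fell (14 and 1 adjusted over the list alone; median 0.28). Of 15 DNA methylation and Polycomb genes 4 rose and none fell (7 adjusted over the list alone; median 0.37): EZH2 (0.71), HDAC2 (0.69), EED (0.54) and SUZ12 (0.29). Without MNNG 2 none of these 4 was called (adjusted p of 0.0527 to 0.413, edgeR), and EED (0.0863) and SUZ12 (0.211) were not called without MNNG 1. The camera adjusted p was 5.75e-05 for ribosome biogenesis (adjusted p = 0.739 with an estimated correlation) and 0.00146 for oxidative phosphorylation (adjusted p = 0.739 with an estimated correlation). For the chromatin list it was 0.00724 (adjusted p = 0.470 with an estimated correlation). Fry gave adjusted p = 0.171 for ribosome biogenesis and adjusted p = 0.0692 for oxidative phosphorylation. Without MNNG 1, 5 ribosome biogenesis, 1 oxidative phosphorylation and 2 chromatin genes rose, and without MNNG 2 the numbers were 4, 0 and 0. The ribosome biogenesis median was 0.67 without PBS A and 0.17 without PBS B, and the chromatin median was 0.24 without PBS A. With library size alone the medians were 0.14 for ribosome biogenesis, 0.11 for oxidative phosphorylation and 0.20 for the chromatin list. Without PBS A, 25 ribosome biogenesis and 9 chromatin genes rose; without PBS B 10 chromatin genes did.

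**Figure D4:**
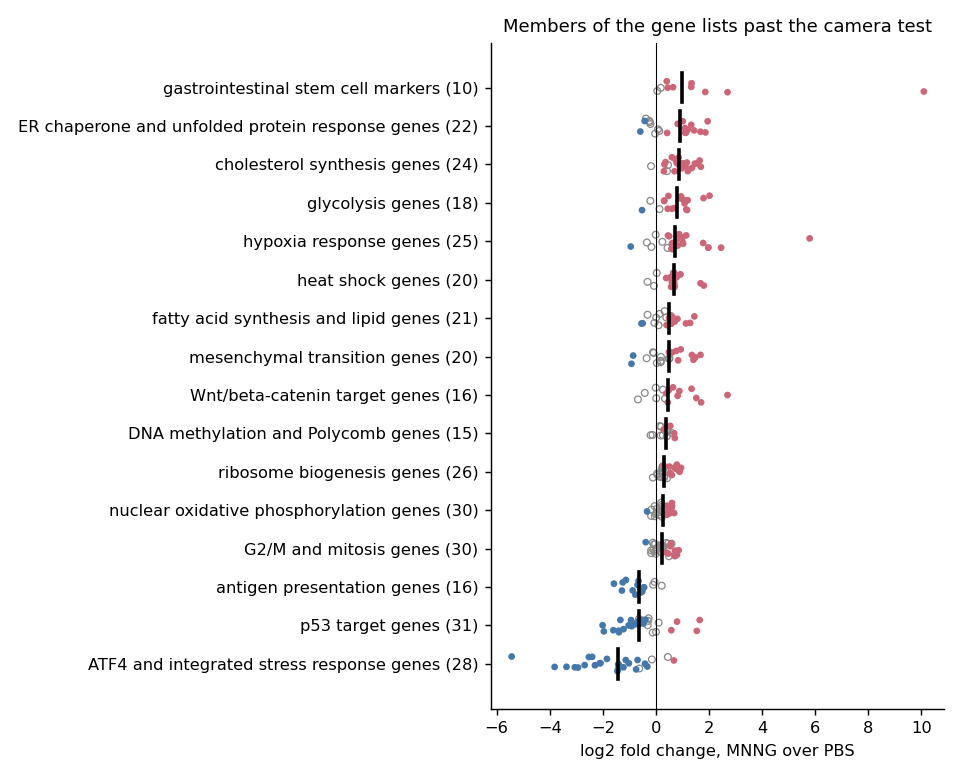
Log2 fold change, MNNG over PBS, of each tested member (points) of the 16 lists past the camera test with a preset correlation, with list sizes in parentheses. Filled points are called members, red for higher and blue for lower, open points are not called, and black bars mark list medians, from -1.43 for the ATF4 list to 0.99 for the stem cell list (0.43 with no filter); the rightmost points of the hypoxia list (CA9) and the stem cell list (OLFM4) rest on 1 and 10 PBS counts.

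In all, 16 of the 37 tested lists passed camera, 13 higher and 3 lower, and 0 passed with an estimated correlation. Fry, which tests a list without comparing it with other genes, called 13: 11 of these 16 (without the p53, G2/M, mesenchymal, oxidative phosphorylation and ribosome biogenesis lists), the cell death regulators and the fibroblast markers.

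Terms over-represented among the higher genes included protein folding, RNA processing and several neurodegenerative diseases. Among GO process terms, protein folding held 80 higher genes of its 147 tested (29.2 expected, adjusted p = 2.42e-17) and mRNA processing 143 of 359 (71.3 expected, adjusted p = 8.93e-16). Cholesterol biosynthesis and mRNA transport also passed. Among KEGG pathways, amyotrophic lateral sclerosis had the lowest p in Fisher's exact test (129 of 317, 72.7 expected, adjusted p = 7.94e-11). The Parkinson, prion, Huntington, Alzheimer and spinocerebellar ataxia terms passed as well. Terms can share genes and their overlap was not counted, so the disease terms are not separate results. The proteasome held 32 of 44 (10.1 expected, adjusted p = 2.95e-10) and the spliceosome 66 of 131 (30.0 expected, adjusted p = 2.95e-10). With Fisher's exact test and Benjamini-Hochberg adjustment, 19 of 328 KEGG and 51 of 2329 GO process terms passed among higher genes. Among lower genes 2 of each kind did: cell adhesion molecules and small cell lung cancer, and immune system process and innate immune response. With calls of at least 2-fold, 0 KEGG and 6 GO terms passed among higher genes and 6 and 3 among lower genes. With terms of 5 to 300 members the numbers were 16 and 40 among higher genes and 2 and 0 among lower genes, since both immune terms hold more members than that.

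The authors' deposited table called 3811 genes at a false discovery rate under 0.05, 2082 higher and 1729 lower. Among the 12791 genes tested here, 3798 were called in the authors' deposited table and 3756 of those also here, 3752 with the same sign. Log2 fold changes of the authors' deposited table and the present fit correlated across genes at a Pearson r of 0.976 and a Spearman rho of 0.965. For CTNNB1 the authors' deposited table gave a log2 fold change of 0.57, for MYH9 -0.42 and for GSK3B 0.03, and its false discovery rate was 0.174 for MYH9 and 0.266 for GSK3B.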

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

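The scalings, filters, tests and thresholds below were planned; leaving out shared members of the p53 list and correcting 2 list medians for GC content and length were chosen after the data were seen. The count of called genes stayed within 1.5 times of 4828 under RLE factors (4803), upper-quartile scaling (4794), library size alone (5044), no filter (4243), a CPM of at least 1 (4561), DESeq2 (4190), limma-voom (4751) and the robust (4846) and legacy (4750) fits. With DESeq2 4129 of the called genes were shared, and with library size alone 3823. Higher genes numbered 1454 and lower genes 3590 with library size alone, which puts the median of all genes at -0.18. With glmTreat, which tests for more than a 1.5-fold change, 786 genes were called, 346 higher and 440 lower, by that stricter question.

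Leaving out 1 library at a time gave 971 to 6845 called genes, 487 to 3490 higher and 484 to 3355 lower. The spread then comes from the 1 remaining pair, wide for PBS and narrow for MNNG, and the lone library is assumed to vary like the other group. MGMT, not called in any of these fits, had log2 fold changes of 0.0168 without PBS B and 0.0232 without MNNG 2, against -0.16 with all libraries and -0.37 without MNNG 1.

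Lists past camera numbered 16 to 19 under the other alternatives, with 19 without PBS A, and 0 with an estimated correlation. That form of camera also takes its degrees of freedom from the 4 libraries and not from the number of genes, and some lists lost their call at an estimated correlation no higher than the preset one. Fry, another test, called 13. Terms over-represented numbered 74, 58 with terms of 5 to 300 members and 15 with calls of at least 2-fold. With 2-fold calls KEGG terms went from 19 to 0 among higher genes and from 2 to 6 among lower genes. Calls shared with the authors' deposited table numbered 3756, and 777 at 2-fold, where fewer genes are called by each. The p53 list had a median of -0.59 without the members chosen as shared with the ATF4 and CHOP response, against -0.62. After the GC and length correction its median was -0.63, and that of the ATF4 list was -1.41, against -1.43.

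No paired analysis was possible because the groups share only replicate number 2 in the labels and the PBS columns carry no sample number. Counts of other splits of the samples do not apply to groups of 2. The planned pseudocount and the filter on FPKM were not run, since the table holds counts. DESeq2, the robust and legacy fits and glmTreat act on the gene test and give no camera value. Depth limits genes near 3 counts, where no fold is given.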

Other observations

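The tests of the CDX2 pattern and of the spread between the PBS libraries were chosen after the result was seen. The tests of GC content and length, and of p53 members chosen as shared, were also added after the data were seen. Their bounds were written before their own results.

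Antigen presentation genes were lower in MNNG cells: of 16 tested, 13 fell and 0 rose (13 adjusted over the list alone; median log2 fold change -0.62; camera, adjusted p = 1.72e-05; adjusted p = 0.470 with an estimated correlation). HLA-F, a non-classical MHC molecule, was at -1.58, HLA-B at -1.28 and the immunoproteasome subunit PSMB8 at -1.25. Without MNNG 1 7 of them fell and without MNNG 2 3 fell. The interferon list did not pass (34 tested, 5 fell and 3 rose; camera, adjusted p = 0.999; median -0.02 and mean 0.00), although STAT2 was at -1.09 and IFIH1 at -1.11. Without PBS A 13 interferon genes rose, without PBS B 11 fell, and without MNNG 1 or without MNNG 2 1 rose and 2 fell. Of 18 xenobiotic genes 5 fell and 5 rose (camera, adjusted p = 0.651), with CYP1B1, an AHR target, at -2.14 and the AHR repressor AHRR at -1.28; without MNNG 1 0 rose and 4 fell, and without MNNG 2 1 rose and 2 fell.

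Of 26 immediate early genes 7 rose and 6 fell (camera, adjusted p = 0.887; median -0.04, mean 0.18), with EGR1 at 1.47 and ETV5 at -1.08. Of 23 cell death regulators 7 fell and 2 rose (camera, adjusted p = 0.314), with HRK at -4.05 and BCL2L1 at -1.06. Of 19 YAP/TAZ targets 8 fell and 2 rose (camera, adjusted p = 0.0658), and of 26 actin and myosin genes 10 rose and 5 fell (camera, adjusted p = 0.124), with TPM3 at 1.01. Of 28 matrix genes 6 fell and 4 rose (camera, adjusted p = 0.814), of 19 TGF-β response genes 4 rose and 4 fell (0.823), of 26 NF-κB genes 7 fell and 4 rose (0.814), of 21 NRF2 genes 6 rose and 6 fell (0.999), and of 25 lysosome and autophagy genes 5 fell and 3 rose (0.447). Of 13 mitochondrially encoded genes 6 fell and 1 rose (0.0533); this list passed under upper-quartile scaling (0.0424), library size alone (0.0181), no filter (0.0478), a CPM of at least 1 (0.0418), limma-voom (0.0487) and without PBS A (0.000535). Of 44 ribosomal protein genes 10 rose and 3 fell (0.0886). Without MNNG 1 or without MNNG 2, at most 3 members of each list in this paragraph rose and at most 5 fell. Calls also moved with the PBS libraries. Without PBS A, 7 cell death, 9 NF-κB and 11 NRF2 genes rose, and 15 matrix, 7 TGF-β response, 9 actin and myosin, 11 lysosome and autophagy, 10 ribosomal protein and 9 mitochondrially encoded genes fell; 2 of the last list rose and 15 ribosomal protein genes did. Without PBS B, 15 matrix, 7 TGF-β response, 6 YAP/TAZ, 5 lysosome and autophagy, 4 mitochondrially encoded and 23 ribosomal protein genes rose, and 11 NF-κB, 11 NRF2, 10 immediate early, 8 lysosome and autophagy and 6 ribosomal protein genes fell. Without PBS A the YAP/TAZ (camera, adjusted p = 0.00176) and matrix (0.0200) lists passed as lower, and without PBS B the ribosomal protein (0.00588) and actin and myosin (0.0104) lists passed as higher.

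Among the tested lists of other cell types camera called none, and fry called the fibroblast list as higher (adjusted p = 0.0306). Of 10 fibroblast markers 4 rose and 2 fell (camera, adjusted p = 0.236; median 0.32, mean -0.01), with POSTN at 3.54 and COL1A1 at 1.52 but COL1A2 at -4.95; without PBS A 4 fell, and 1 fell without MNNG 1 or without MNNG 2, where COL1A2 was not called (adjusted p of 0.0751 and 0.0821, edgeR). Of 6 endothelial markers 1 rose (FLT1, 1.61; camera, adjusted p = 0.651; 1 fell without PBS A), and of 7 squamous markers IVL rose (2.47) and KRT17 fell by 1.37 (camera, adjusted p = 0.622); IVL was not called without MNNG 2 (adjusted p = 0.0571, edgeR), and 4 squamous markers rose without PBS B. Of 3 tested immune markers 0 were called (1 rose without PBS B), and of 4 neuroendocrine markers 2 fell, NCAM1 (-1.41) and ENO2, the latter not called without MNNG 1 or without MNNG 2 (adjusted p of 0.0862 and 0.216, edgeR).

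CDX2, REG4 and OLFM4 were near 0 in PBS cells and abundant in MNNG cells. Intestinal RNA or cells mixed into the MNNG libraries would bring the other intestinal transcripts. The 19 listed genes other than CDX2 and REG4 had a summed CPM of 0.00265 times that of CDX2. The whole list, REG4 included, summed to 3255 CPM in MNNG cells, of which CDX2 made 3155. Of these 19 genes, left after the called members were taken out, 0 reached a CPM of 1 and lay above both PBS libraries. That count was likely in advance, since a gene so raised would probably have been called, and it is not used here. Of all 21 listed genes, 3 reached a CPM of 1 in both MNNG libraries and 1 did in both PBS libraries, and 12 had no counts in any library. The summed CPM and the counts over all listed genes argue against such a mixture and against a broad programme among the listed genes. CDX2 lay above 100% of the other transcription factor genes of the table, ahead of YBX1 at 1480 CPM, a level that could come from an introduced CDX2 sequence as well as from the cells' own gene. Counts per gene cannot separate these, and the MNNG treatment stays open, untested. The labels give WT as the genotype of the PBS samples only, so the groups may differ in more than the treatment.

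The ATF4 list was lower in MNNG cells. On the spread between the PBS libraries, the lower PBS library lay above the higher MNNG library by a median of 1.14 on the log2 scale (interquartile range 0.516 to 2.01). A positive gap was likely in advance, since the list was taken up for its called decreases. The size of the gap exceeded the list's median difference of 0.40 between PBS A and PBS B. A trend with GC content and length is argued against as the whole cause, since the correction kept 98.9% of the list median. Lower integrated stress signalling after MNNG may underlie it, as a hypothesis not tested here, and culture differences such as medium or density stay open as well.

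More p53 targets fell than rose in MNNG cells (17 against 4; camera, adjusted p = 0.00113; fry, adjusted p = 0.171). For the spread between the PBS libraries the median gap was 0.251 on the log2 scale (interquartile range -0.155 to 0.666). This was less than the list's median difference of 0.40 between PBS A and PBS B. The gap lay between the bounds set for either reading, chosen after the result was seen and unlike those of the ATF4 list. The PBS spread cannot be told apart from the treatment. The p53 and ATF4 lists share no gene. GDF15, BBC3, TNFRSF10B, PMAIP1, SESN1 and GADD45A were chosen as shared with the ATF4 and CHOP response. Without them the list still lay -0.58 from the median of all tested genes, with 14 of 25 members lower and 4 higher. The decrease was thus not confined to the genes left out. With 17 members called lower, leaving out so few genes could hardly bring the median near that of all tested genes. The outcome was therefore likely in advance and gives no separate support. The comparison also does not test whether other members respond to ATF4 or CHOP. The GC and length correction kept 101% of the list median. Whether the p53 response was lower is left open by the PBS spread. RNA levels of these targets also do not measure p53 activity, which was not tested.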
